A study of Mus musculus and Gallus gallus with 39 samples.

How the data were processed

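Small RNA libraries from dorsal root ganglia, the clusters of sensory neurons beside the spinal cord, were analysed in 39 samples. Of these, 12 were labelled chicken and 27 mouse. The deposited tables, one per species, hold raw read counts, per the file headers, for every distinct sequence tag and for each miRNA code. Those headers name miRProf as the program that made them, with reads filtered by length, low complexity and abundance. The authors kept only reads that match the genome, per the file headers, and assigned them to mature miRNAs of miRBase with 0 mismatches. The headers also record that variants, arms and organisms were combined, so that 1 code stands for all forms of a miRNA number and let-7 is 1 code. The genome builds are mm9 and galGal4, per the submitters' processing notes. The aligner's settings and the program versions are not given in the sources used here. A further 12 chicken and 27 mouse columns of normalised values, made from the same reads, were not analysed here.

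Code totals were rebuilt from the tag lines, 2345 for chicken and 6039 for mouse, with each tag counted once. The need arose because 77 chicken and 95 mouse tags stand under more than 1 code. Codes that shared over 50% of the reads of the smaller code were merged, which joined 8 pairs, among them miR-103 with miR-107 and miR-17 with miR-106. A tag still shared went to the more abundant code. This gave 131 chicken and 540 mouse codes. Only 16 reads stood in the deposited code totals but in no tag line, and these were left out. Codes are written below as miRNA names, and values are for the code as a whole.

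Samples were grouped by species, labelled stage, genotype and culture agent, and axial level (brachial, thoracic or lumbar) was a term of the model. Axial labels of 2 libraries, chicken E9 lumbar and mouse E11.5 brachial, differ between label fields, and the level in the title was used. Counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter grouped by stage (minimum count of 10), and the quasi-likelihood test of stage plus level. The mouse fit held the 16 wild-type dissected libraries, the chicken fit all 12 libraries, and the fit for the TrkC mutant the 16 plus the 2 mutant libraries with a genotype term. Benjamini-Hochberg adjustment ran over the miRNAs of a comparison, with a threshold of 0.05. In all, 12 comparisons were tested. Log2 fold changes are given with a standard error (SE) derived from the test, the absolute change divided by the square root of its F statistic. Levels are given as mean ± SD of TMM-scaled CPM. Folds against a group with no reads used a floor of 3 reads in each library of that group.

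Lists of miRNAs, 15 in number, covered the let-7 family, neurons, the sensory cluster, miR-17-92 and paralogs, pluripotency, Hox clusters, the Dlk1-Dio3 cluster, signal responsive miRNAs, glia, blood, muscle, mesenchyme, endothelium, epithelium and liver. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. For the cultured ganglia, 1 library per agent left no spread to test against. Each agent was compared with the control as a log2 ratio of TMM-scaled counts with a prior count of 1, for codes with at least 100 reads and 50 CPM in one of the libraries. Exact binomial intervals at 95% (Clopper-Pearson) accompany these ratios, and list medians were placed among 10000 random lists matched on expression. Detected miRNAs were counted at 10 reads or more after each library was thinned to the smallest library of its species, and compared by exact permutation tests with scipy 1.17.1. Shares of reads carry 95% Wilson intervals. Intervals and floors cover counting error only, because the reads carry no molecular identifiers.

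The groups, tests, lists, alternatives and the rule for named miRNAs were fixed before the data were examined, apart from the additions named here and in later parts. The rule took, per comparison, the 8 largest rises and 8 largest falls past the threshold with at least 100 CPM in one group. It added up to 3 members per list with members past the threshold, miR-10 and miR-196 in axial comparisons, and the 3 highest and 3 lowest codes per agent. Alternatives were RLE size factors, total counts without scaling, no count filter, DESeq2 1.42.0, no axial term, each library left out in turn, the libraries with conflicting labels left out, brachial libraries only for the TrkC mutant, other detection limits, and a prior count of 5 and another reference for the agents. Sequencing pool as a term, the omission of the mouse-labelled libraries under 1% Dlk1-Dio3 reads, and single-library omissions for the detection counts were added after the data were seen. So were the permutation test of miR-196 order and Fisher's exact test of the miRNAs that fell. The pool of each library was read from the column names. Among the wild-type dissected mouse libraries only E13.5 occurs in both pools, so in that fit the pool term rests on the lumbar E13.5 library.

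The fit was tested on simulated counts drawn at the means and library sizes of the real codes, with up to 40 codes changed by known folds because so few codes are measured. With the observed spread, 38.5% of codes changed 16-fold were recovered for mouse E13.5 against E12.5 (222 codes), 87.5% for chicken E7 against E6 (85 codes), 69.2% for mouse lumbar against brachial (227 codes), and 0% for the TrkC mutant (234 codes). For 4-fold changes the observed spread gave 0%, 40%, 7.7% and 0%, in the same order. At an assumed biological coefficient of variation of 0.3, at least 90.9% of 4-fold changes were recovered, with 3 of 182 unchanged codes called for lumbar against brachial. The common value in the fits was higher, at 0.85 (mouse), 0.61 (chicken) and 1.07 (TrkC mutant). The leading tags of the named miRNAs were matched to GRCm38 with the GENCODE M21 annotation, and all 43 codes looked up had a match. The agent ratios, on 47 simulated codes, returned the known log2 change within 0.14. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for the remaining steps.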

Results

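Mature miRNAs were measured by small RNA sequencing in dorsal root ganglia, to follow their expression by place and time in the embryo and after growth factors and signalling agonists. The 12 chicken-labelled libraries were 1 of E4, 3 each of E5, E6 and E7, and 2 of E9. Of the 27 mouse-labelled libraries, 16 were wild-type dissected ganglia: 1 of E10.5, 2 of E11.5, 3 each of E12.5, E13.5, E18.5 and P16, and 1 of E14.5. The other mouse-labelled libraries were 9 of cultured E12.5 thoracic ganglia and 2 of TrkC mutant brachial ganglia, at E11.5 and E14.5. Libraries held 116416 to 2755897 miRNA reads in chicken and 48743 to 1521177 in mouse. Replicates of a stage are ganglia of different axial levels, and nothing in the labels says whether they came from separate animals, so the p-values measure only the spread between these libraries.

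A few abundant miRNAs led both tables. In the mouse-labelled libraries miR-183, a sensory neuron miRNA, took 10.9% ± 3.22 of reads (SD, n = 27), let-7, a family tied to developmental timing, 9.35% ± 3.89, miR-30 7.01% ± 2.10, and miR-19 5.79% ± 4.98. In the chicken-labelled libraries let-7 took 25.3% ± 9.66 (n = 12), miR-183 11.1% ± 6.01 and miR-30 7.20% ± 1.30. The leading 6 codes together took 42.8% ± 3.89 of mouse and 56.1% ± 3.94 of chicken reads. miRNAs named below for comparisons or settings outside the naming rule were chosen after their values were seen.

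The Dlk1-Dio3 cluster, a large miRNA cluster of placental mammals, divided the mouse-labelled libraries. It took 3.83% to 7.90% of reads (median 5.59%) in 15 libraries and 0.00145% to 0.0259% (median 0.00408%) in the other 12. Those 12 were labelled E13.5 thoracic, E14.5 wild type, all 3 of E18.5, all 3 of P16, and the cultured control, NT3, Wnt5a and Wnt3a. miR-93 and miR-25 lay at 10901 to 36764 and 6983 to 21829 CPM (unscaled) in the 15 libraries, but at 0.823 to 14.9 and 0 to 12.9 CPM in the 12. After thinning to one depth, 53 to 66 miRNAs were detected in the 12 and 129 to 154 in the 15, although the 12 were deeper (median 975402 against 414994 reads). The highest share among the 12, in the E13.5 thoracic library, had a 95% Wilson interval of 0.0204% to 0.0329%.

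**Figure D1:**
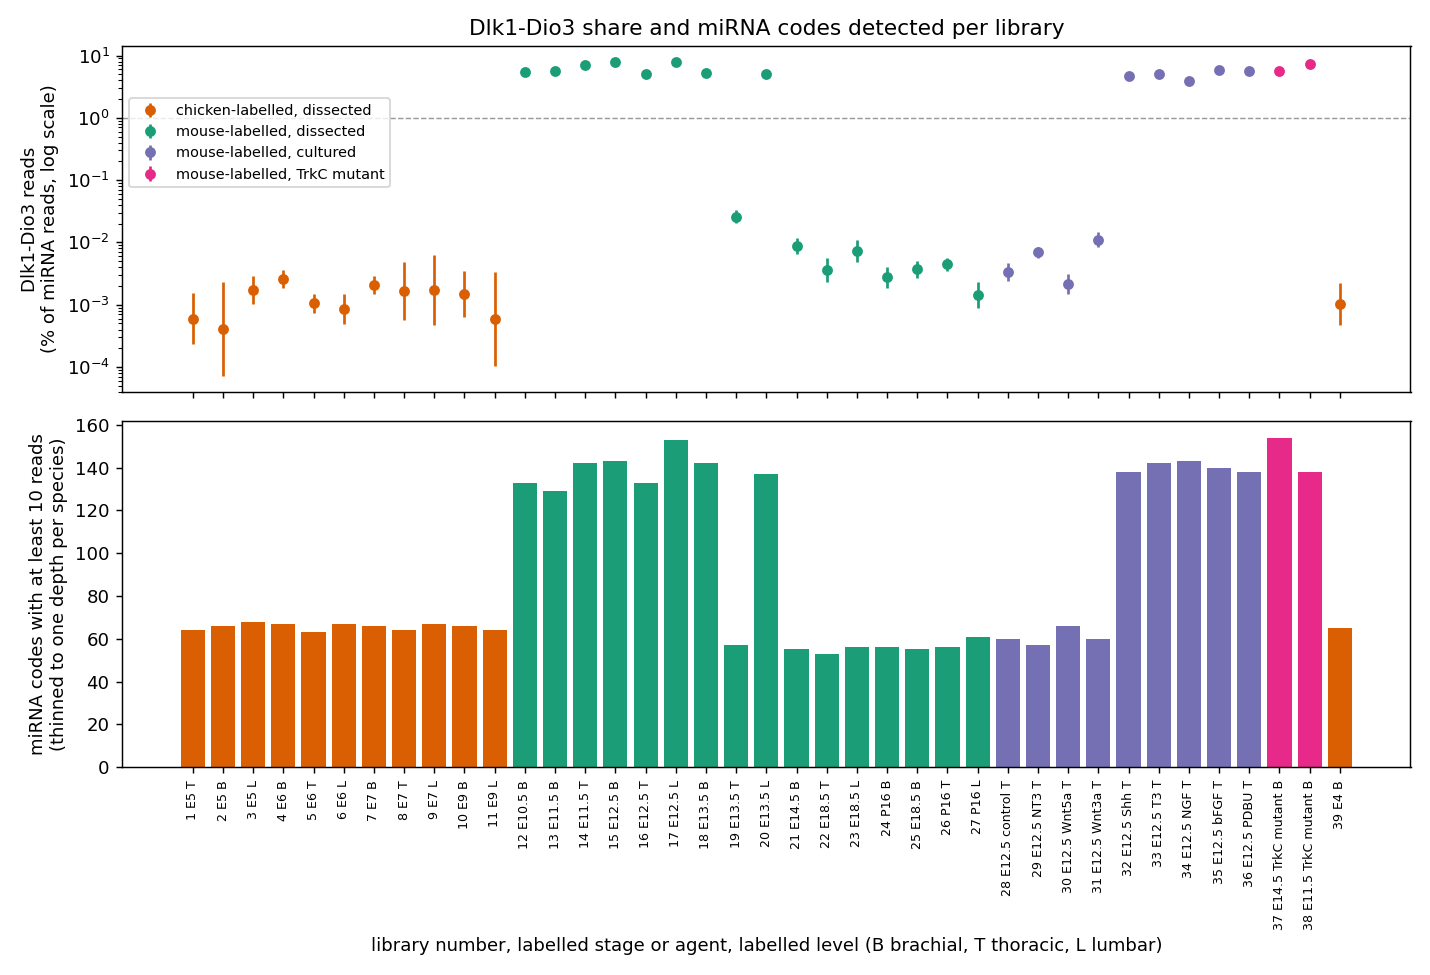
Upper panel: percent of miRNA reads from the Dlk1-Dio3 cluster in each of the 39 libraries (log axis, bars are 95% Wilson intervals, dashed line at 1%). Chicken-labelled libraries were counted after a filter for reads that match the chicken genome. Lower panel: miRNA codes with at least 10 reads after thinning to one depth per species. Of the mouse-labelled libraries, 12 sit at 0.0259% or less and at 53 to 66 codes, and the other 15 above 3.83% and at 129 to 154 codes.

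The chicken-labelled libraries held 142 reads of Dlk1-Dio3 miRNAs among 10104291 (miR-377 with 122, miR-329 with 15 and miR-341 with 5). Only reads that match the chicken genome were kept for these libraries, so this low share does not tell the species of the RNA. miR-2954, a miRNA of birds, had 22 reads in all, from 0 to 5 per library, and was seen in 11 of the 12 libraries. All comparisons below use the labelled groups, and the place of the compared mouse-labelled libraries in this division is given with each comparison. Each comparison speaks of its labelled stage, genotype or agent only if the labels hold.

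miR-196, encoded within the Hox clusters and a marker of caudal position, gave a check of the axial labels. Pairs were formed within species and, in mouse, among libraries whose barcode partner in the other sequencing pool carries the same species label. Among 143 pairs of different labelled level, the more caudal library held more miR-196 in 71 (49.7%, permutation test, one-sided p = 0.53). Mouse-labelled lumbar libraries ranged from 39.7 CPM (unscaled; E12.5) to 9214 (E13.5). The brachial libraries of the TrkC mutant held 12629 CPM at E14.5 (95% Wilson interval 12294 to 12973) and 61.5 at E11.5 (43.6 to 86.8).

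**Figure D2:**
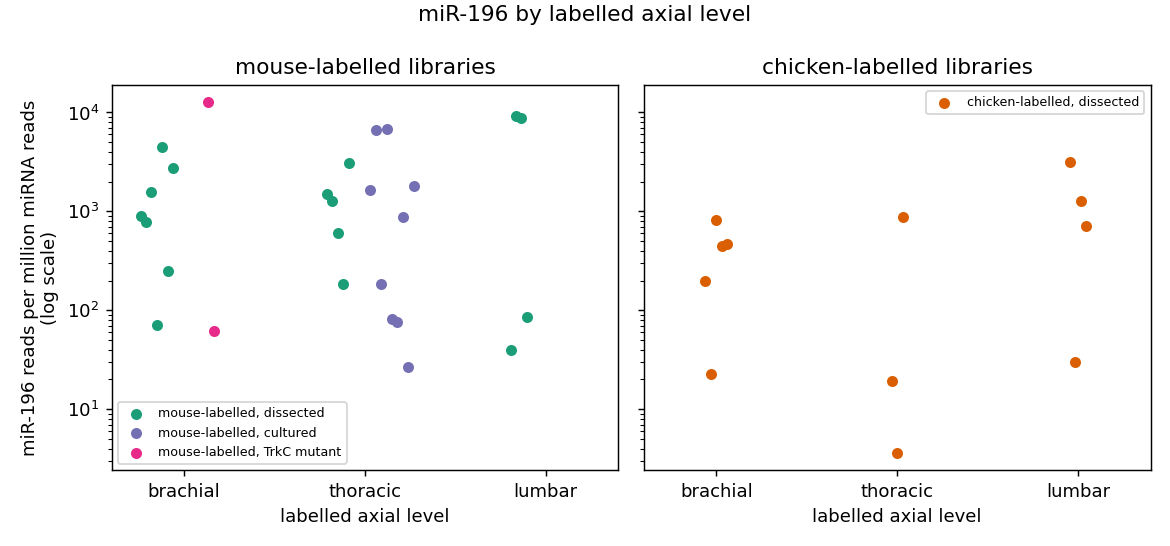
miR-196 reads in each library (y axis, log scale, unscaled CPM) by labelled axial level, with mouse-labelled libraries on the left and chicken-labelled on the right. Mouse-labelled lumbar libraries spread from 39.7 to 9214 CPM.

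Between E11.5 and E12.5, while sensory neurons are still being born, no mouse miRNA passed the test. let-7 lay at 84953 ± 305 CPM at E11.5 (n = 2) and 84765 ± 14504 at E12.5 (n = 3), and miR-9, a neuronal miRNA, at 5808 ± 856 and 10406 ± 1699, a log2 fold change of 0.98 (SE 0.78). edgeR's quasi-likelihood test called 0 of 245 miRNAs after Benjamini-Hochberg adjustment, with 1 at an unadjusted p under 0.05, and DESeq2 called 0. None of the lists passed. All 5 libraries held over 5% Dlk1-Dio3 reads. Their place on 1 side of the division does not check their stage labels. The barcode partner of the lumbar E12.5 library is labelled brachial E14.5 TrkC mutant, and the other partners are cultured E12.5 ganglia.

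Between E12.5 and E13.5, 2 mouse miRNAs rose and none fell. Both belong to the miR-17-92 clusters and paralogs, which are expressed in proliferating cells. miR-363 (Mir363, GRCm38 chromosome X, 52741693 to 52741767) rose from 268 ± 255 to 32781 ± 55996 CPM (n = 3 per stage), a log2 fold change of 5.97 (SE 1.33, adjusted p = 0.0329). miR-20 (Mir20a, chromosome 14, 115044157 to 115044263, in an exon of Mir17hg) rose from 11325 ± 9215 to 61976 ± 63860 CPM, a change of 2.32 (SE 0.56, adjusted p = 0.0375). The thoracic E13.5 library, with 0.0259% Dlk1-Dio3 reads against over 5% in the other 5 libraries, supplied most of both means: miR-363 stood at 97438 CPM there against 703 in the brachial and 201 in the lumbar library.

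Among the lists, the miR-17-92 members shifted upward from E12.5 to E13.5, with 2 of 8 passing, 5 adjusted over the list alone, and a median log2 change of 1.39 (camera adjusted p = 6.38e-05, and adjusted p = 0.0284 with an estimated correlation). Other lists were called only at the preset correlation. The 44 Dlk1-Dio3 members had a median of -1.05 (adjusted p = 6.38e-05, and adjusted p = 0.426 with an estimated correlation). Mesenchyme (5 members, median 1.28) had adjusted p = 0.000155, and adjusted p = 0.0646 with an estimated correlation. Neuronal (11, median 0.62) and signal responsive (5, median 0.99) lists had adjusted p = 0.0257 and 0.0235, and adjusted p = 0.346 and 0.298 with an estimated correlation. No member of these 4 lists passed singly, and adjusted over the list alone 1 mesenchyme and 1 signal responsive member did. Without the libraries under 1% Dlk1-Dio3 reads, the miR-17-92 list (median 1.06, 0 passed, also 0 adjusted over the list alone) had adjusted p = 0.000636, and adjusted p = 0.382 with an estimated correlation. Mesenchyme then had adjusted p = 0.0328, and adjusted p = 0.382 with an estimated correlation. The Dlk1-Dio3 list had a median of -0.13 (adjusted p = 0.136), and the neuronal and signal responsive medians turned to -0.44 and -0.13 without a call.

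The E13.5 test called 2 of 245 miRNAs with 13 at an unadjusted p under 0.05, and DESeq2 called 2 (miR-363 and miR-302). Without the thoracic E13.5 library, neither call remained (miR-363 1.05, adjusted p = 0.891; miR-20 1.56, adjusted p = 0.738) and only miR-219, a miRNA of myelinating glia, passed at 3.41. Without all libraries under 1% Dlk1-Dio3 reads, miR-219 again was the only call (3.66, adjusted p = 0.00379), and without the lumbar E13.5 library, which leaves the compared libraries in 1 pool, 4 passed (miR-363, miR-20, miR-92 and miR-199). Without the lumbar E12.5 library miR-20 missed the threshold (1.97, adjusted p = 0.135), and RLE factors or total counts left 0 calls.

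Between E13.5 and E18.5, 152 of 245 mouse miRNAs changed, 9 upward and 143 downward. Of the 11 neuronal miRNAs tested, 4 rose. miR-137 (Mir137, GRCm38 chromosome 3, 118433857 to 118433929) went from 10620 ± 7317 to 44433 ± 11272 CPM (n = 3 per stage), a log2 fold change of 2.14 (SE 0.60, adjusted p = 0.00502). miR-128 went from 7406 ± 11916 to 23890 ± 9335 CPM, a change of 2.49 (SE 0.97, adjusted p = 0.0287), and miR-218 from 1820 ± 820 to 8723 ± 3021, a change of 2.36 (SE 0.85). The fourth was miR-138 (1.92), 1 of the 11 passed adjusted over the list alone, and the list median was 1.42 (camera adjusted p = 4.03e-08, and adjusted p = 0.0998 with an estimated correlation). The other named rises were miR-101 (2.31), miR-103/107 (2.27), miR-100 (1.94) and miR-19 (1.42). The thoracic E13.5 library, with 0.0259% Dlk1-Dio3 reads against 5.29% in the brachial and 5.05% in the lumbar library, stood apart for several of these. It held 21165 CPM of miR-128 against 508 and 545 in the brachial and lumbar libraries, and 18682 of miR-100 against 2737 and 1307, both within the E18.5 range. For miR-101 it held 19213 against 746 and 4603, below the lowest E18.5 value of 24656.

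Imprinted-cluster miRNAs fell together between these labelled stages, in a contrast that also crosses the Dlk1-Dio3 division. The E18.5 libraries hold at most 0.00733% Dlk1-Dio3 reads, and within E13.5 the thoracic library, at 0.0259%, was already low against 5.29% and 5.05%. Neither the falls below nor the rises above can therefore be assigned to stage. In cultured ganglia of 1 labelled stage, E12.5, miR-137 lay at 37945 to 91897 CPM in the control, NT3, Wnt5a and Wnt3a libraries, all under 1%. It lay at 1332 to 5228 in the rest. For miR-128 the ranges were 22609 to 40340 and 605 to 1296, and for miR-218 they were 4923 to 8678 and 698 to 2085. Of 44 tested Dlk1-Dio3 members, 42 fell, 43 adjusted over the list alone, and 31 had no read in any E18.5 library. miR-127 (Mir127, GRCm38 chromosome 12, 109592846 to 109592915, opposite an exon of Rtl1) dropped from 4646 ± 4132 to 1.34 ± 1.36 CPM, a log2 fold change of -11.43 (SE 1.64, adjusted p = 3.11e-05). miR-541 and miR-369 (chromosome 12, 109743418 to 109743496, in an exon of Mirg) changed by -11.01 and -11.32. miR-411 was at least 194-fold lower, miR-376 at least 175-fold, miR-300 at least 169-fold, miR-136 at least 180-fold and miR-409 at least 128-fold, all with 0 reads at E18.5. The list median was -9.34, or -4.96 with members at 0 set to the floor (camera adjusted p = 5.01e-06, and adjusted p = 0.419 with an estimated correlation).

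The other 101 miRNAs that fell lie outside this cluster. miR-335 (Mir335, in an intron of Mest) was at least 212-fold lower at E18.5, miR-708 at least 142-fold and miR-744 at least 130-fold. miR-93 and miR-25, each annotated within an exon of Mcm7 on GRCm38 chromosome 5 (138165523 to 138165610 and 138165321 to 138165404), changed by -11.48 and -10.59, miR-93 from 11890 ± 10759 to 4.31 ± 1.00 CPM. With the rise of miR-19, 3 of 8 miR-17-92 members passed, also 3 adjusted over the list alone, and the list's median (0.43) and mean (-2.16) differed in sign while camera placed it above other codes (adjusted p = 0.0482, and adjusted p = 0.199 with an estimated correlation). miR-615, from the Hoxc cluster (-6.30, 1 of 3 Hox members), miR-98 of the let-7 family (-6.86, 1 of 2), and the epithelial miR-203 (-5.98, 1 of 4) fell. Of 7 blood members, miR-486 and miR-155 fell, at least 3.88-fold and at least 1.99-fold. Counts adjusted over the list alone were the same for these 4 lists.

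Signal responsive miRNAs (5 tested, none passed, median 1.10) had a camera adjusted p = 0.00103, and adjusted p = 0.199 with an estimated correlation. The blood and Hox medians (0.05 and 0.02) and means (-2.14 and -1.71) differed in sign, and camera called neither list. None of the 5 mesenchyme, 4 muscle, 3 sensory cluster, 2 glia, 1 endothelium, 1 liver and 1 pluripotency members passed. The mesenchyme, muscle and epithelium medians were -0.50, -0.12 and -1.41, while camera placed these lists above other codes without a call (adjusted p = 0.247, 0.247 and 0.601). In the sensory cluster, miR-183 lay at 123131 ± 33278 CPM at E18.5 against 77483 ± 5544 at E13.5, and miR-182 at 19010 ± 5555 against 48148 ± 34644. Of the 143 miRNAs that fell, 13 (9.09%) were among those with at least 10 reads in the chicken table, against 79 of the other 102 (77.5%; Fisher's exact test, two-sided p = 3.11e-29). Of the 143, 42 belong to the mammal-only Dlk1-Dio3 cluster, against 2 of the 102, so part of this difference was given in advance. The test counts members of 1 cluster as independent, and the codes outside it were not tested apart.

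**Figure D3:**
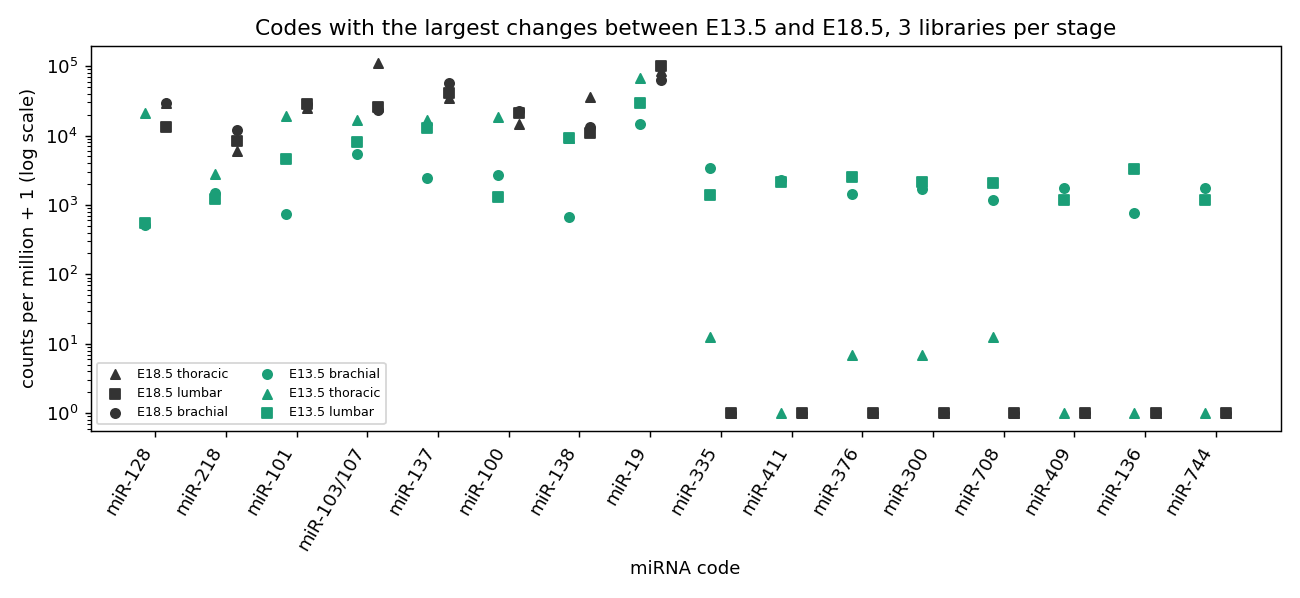
Scaled CPM plus 1 (log axis) of the named rises and falls between E13.5 (green) and E18.5 (black), with 1 point per library and marker shape for axial level. The thoracic E13.5 library holds 11.7 CPM of miR-335 and 0 of miR-136, against 763 to 3440 in the other E13.5 libraries and 0 at E18.5.

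edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave these 152 calls, with 165 at an unadjusted p under 0.05 and 153 by DESeq2. The median log2 change of all 245 was -5.65, and RLE factors and total counts moved it by a further -0.29 and -0.37. The 3 E18.5 libraries hold at most 0.00733% Dlk1-Dio3 reads, so this comparison cannot be made without such libraries. With sequencing pool as a term 119 passed, 115 of them among the 152. That term rests on the lumbar E13.5 library, because only E13.5 occurs in both pools, and it cannot separate pool or the Dlk1-Dio3 division from stage. The count of calls, without a pool term, was 67 without the brachial E13.5 library, 97 without the lumbar E13.5, 98 without the brachial E18.5 and 202 without the thoracic E13.5.

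Among the named rises, miR-137 passed in every omission of a library, which does not tell stage from the Dlk1-Dio3 division. Calls kept or lost with the pool term, given next, do not tell pool from stage. With pool as a term, miR-137 (1.66, adjusted p = 0.110), miR-218 (2.68, adjusted p = 0.112), miR-138 (0.97, adjusted p = 0.488), miR-101 (2.62, adjusted p = 0.0565) and miR-19 (1.20, adjusted p = 0.131) missed the threshold, so 3 of the 4 neuronal calls ended, and of the falls miR-486 (adjusted p = 0.0534) and miR-155 (adjusted p = 0.0933) missed it. Without the brachial E13.5 library, miR-128 (1.59), miR-218 (2.23), miR-101 (1.59), miR-100 (1.43), miR-138 (1.26) and miR-19 (1.08) missed the threshold. Without the brachial E18.5 library, miR-128 (2.10), miR-218 (2.01), miR-101 (1.90), miR-100 (1.83) and miR-138 (1.71) did, and without the lumbar E13.5 library miR-128 (1.65), miR-218 (1.97) and miR-100 (1.09). Without the lumbar E18.5 library it was miR-218 (2.24), miR-100 (1.49) and miR-19 (0.93), and without the thoracic E18.5 library miR-103/107 (1.58) and miR-138 (1.60). Of the falls, miR-486, miR-155 and miR-203 missed it without the brachial E13.5 (-6.01, -4.96 and -5.00), the lumbar E13.5 (-6.77, -6.22 and -5.87) or the brachial E18.5 library (-6.85, -5.61 and -6.02), and miR-98 without the lumbar E13.5 library (-5.46).

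Between E18.5 and P16, the postnatal step, no mouse miRNA passed. miR-19 lay at 243337 ± 97107 CPM at P16 and 83332 ± 18125 at E18.5 (n = 3 each), a log2 change of 1.44 (SE 0.48) with an unadjusted p under 0.05 by edgeR but an adjusted p = 1. The muscle miRNAs miR-1 and miR-133 lay at 4519 ± 2202 against 1068 ± 585 and 344 ± 210 against 59.1 ± 24.9. The muscle list (4 members, 0 passed, also 0 adjusted over the list alone, median 1.13) had a camera adjusted p = 0.00247, and adjusted p = 0.216 with an estimated correlation. edgeR and DESeq2 each called 0 of 245, with miR-19 the 1 code at an unadjusted p under 0.05. All 6 libraries are under 1% Dlk1-Dio3 reads, and their barcode partners are all labelled chicken, of E5 or E6 for E18.5 and of E6 or E7 for P16.

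The number of miRNAs detected at equal depth followed the same division. It was 143 ± 10.0 at E12.5 and 112 ± 47.7 at E13.5 (n = 3 each, exact permutation test, two-sided p = 0.4), 54.7 ± 1.53 at E18.5 (exact p = 0.1 against E13.5) and 57.7 ± 2.89 at P16 (exact p = 0.3 against E18.5). In chicken it was 66.0 ± 2.00 at E5, 65.7 ± 2.31 at E6 and 65.7 ± 1.53 at E7 (exact p = 1 for both steps). The smallest p that 3 against 3 libraries allow is 0.1. Without the thoracic E13.5 library the E13.5 mean differed from E12.5 by -3.50.

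Between E5 and E6, no chicken miRNA passed. miR-196 had the smallest p, at 1027 ± 1588 CPM at E5 and 17.2 ± 12.6 at E6 (n = 3 each), a log2 change of -4.92 (SE 1.27, adjusted p = 0.199). The E5 libraries held 18.6, 206 and 2857 CPM, with barcode partners labelled brachial, thoracic and lumbar in that order, and the E6 partners are labelled brachial, brachial and thoracic, so stage and partner level differ together here. The blood miRNAs miR-451 and miR-144 lay at 454 ± 187 and 278 ± 67.8 at E5 and at 3636 ± 2805 and 2040 ± 1546 at E6, changes of 3.02 (SE 1.04) and 3.03 (SE 1.15) that did not pass. All 4 blood members passed adjusted over the list alone and 0 over all miRNAs (camera adjusted p = 0.00754, and adjusted p = 0.735 with an estimated correlation). Over the list alone, 2 Hox, 1 glia and 1 liver member also passed. miR-338, a glial miRNA, lay at 1700 ± 682 and 7986 ± 3191, a change of 2.43 (SE 0.70, adjusted p = 0.206). By stage, the E5 partners are labelled E14.5, E18.5 and E18.5, and the E6 partners P16, E18.5 and P16. Stage and partner stage therefore also differ together for the blood miRNAs and miR-338.

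For E6 against E5, edgeR called 0 of 88 with 16 at an unadjusted p under 0.05, while DESeq2 called 6 (miR-196 lower, and miR-144, miR-29, miR-338, miR-34 and miR-451 higher). Without the brachial E6 library 12 passed in edgeR, among them miR-196 (-5.51), miR-338 (3.01), miR-451 (3.72) and miR-144 (3.78).

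Between E6 and E7, 1 chicken miRNA rose. miR-196 went from 17.2 ± 12.6 to 1062 ± 339 CPM (n = 3 each), a log2 fold change of 6.63 (SE 1.33, adjusted p = 0.0291). It was higher in each E7 library than in any E6 library. By axial order, miR-196 in chicken-labelled libraries followed the labels in 63.8% of pairs and the level of the barcode partner in 95.1%. Those partners are labelled brachial, brachial and thoracic for the E6 libraries and lumbar, thoracic and thoracic for the E7 libraries, so stage and partner level differ together in this comparison. Among miR-17-92 members, miR-20 lay at 1719 ± 447 and 15737 ± 12351 (2.90, SE 0.72, adjusted p = 0.0791) and miR-17/106 at 1578 ± 808 and 17615 ± 13698 (3.28, SE 0.96, adjusted p = 0.117). That list had 0 of 6 members past the threshold, 4 adjusted over the list alone, a median of 2.82 and a camera adjusted p = 0.000286, and adjusted p = 0.732 with an estimated correlation. The brachial E7 library held only 2546 CPM of miR-20 and 1876.5 of miR-17/106, the latter within the E6 range of 645 to 2062. Its barcode partner and those of the E6 libraries are labelled P16 or E18.5. The partners of the thoracic and lumbar E7 libraries are cultured E12.5 ganglia.

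For E7 against E6, edgeR called 1 of 88 with 13 at an unadjusted p under 0.05, and DESeq2 called 5 (miR-196, miR-20, miR-17/106, miR-18 and miR-103/107). The miR-196 call ended without the thoracic E7 (4.91, adjusted p = 0.0876), the thoracic E6 (5.83, adjusted p = 0.113), the lumbar E6 (6.44, adjusted p = 0.293) or the E9 library with conflicting labels (6.61, adjusted p = 0.0635), whereas 36 miRNAs passed without the brachial E7 library and 8 without the brachial E6 library.

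Between E7 and E9, no chicken miRNA passed. The muscle miRNA miR-206 lay at 387 ± 507 CPM at E7 (n = 3) and 20.7 ± 11.9 at E9 (n = 2), a log2 change of -4.01 (SE 1.23, adjusted p = 0.308), and miR-338 at 4911 ± 3138 and 447 ± 267 (-3.60, SE 0.87, adjusted p = 0.122). The brachial E7 library held the highest E7 values, 968 CPM of miR-206 against a lowest of 38.3, and 38356 of miR-1 against 2490. Its barcode partner is labelled P16, while those of the other E7 and both E9 libraries are cultured E12.5 ganglia. Stage and partner stage are thus not separate here. Of 3 muscle members 0 passed, 2 adjusted over the list alone, with a median of -2.64 (camera adjusted p = 0.00925, and adjusted p = 0.706 with an estimated correlation). edgeR called 0 of 88 with 6 at an unadjusted p under 0.05, and DESeq2 called 2, miR-206 and miR-338.

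Axial level, the place part of the design, gave no call in mouse. Since miR-196 followed the labelled level in only 49.7% of pairs, the contrasts by level, with or without calls, speak of place only if the labels hold. miR-196 lay at 4397 ± 5081 CPM in lumbar (n = 4) and 1736 ± 2134 in brachial libraries (n = 7), a log2 change of 1.51 (adjusted p = 0.999), and miR-10, also of the Hox clusters, at 45700.2 ± 25881 and 59652 ± 17676 (-0.60). The muscle list was placed higher in lumbar ganglia (4 members, 0 passed, also 0 adjusted over the list alone, median 1.22, camera adjusted p = 0.00102, and adjusted p = 0.137 with an estimated correlation). The mesenchyme and miR-17-92 lists were placed lower (medians -0.50 and -0.44, adjusted p = 0.00894 and 0.0339, and adjusted p = 0.137 for both with an estimated correlation). edgeR called 0 of 245 with 3 at an unadjusted p under 0.05, and DESeq2 called 0. Of these libraries, 2 of the 4 lumbar and 3 of the 7 brachial hold under 1% Dlk1-Dio3 reads. Without them, 5 miRNAs were higher in libraries labelled lumbar: miR-1 (2.22), miR-133 (2.74), miR-206 (3.10), miR-138 (2.86) and miR-136 (2.26). The lumbar side was then only the E12.5 and E13.5 libraries, which hold 39.7 and 9214 CPM (unscaled) of miR-196. The barcode partner of the lumbar E12.5 library is labelled brachial. The muscle list was then called with 3 of 4 members (also 3 adjusted over the list alone, median 2.48, adjusted p = 5.14e-05, and adjusted p = 0.418 with an estimated correlation), and the mesenchyme and miR-17-92 lists were not (adjusted p = 0.168 and 0.0671).

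Thoracic ganglia, which supply no limb, were compared with the mean of brachial and lumbar. miR-10 lay at 98868 ± 72562 CPM in thoracic (n = 5) and 54579 ± 20928 in limb-level libraries (n = 11), a log2 change of 0.85 (adjusted p = 0.616), and miR-196 at 1802 ± 2211 and 2704 ± 3505 (0.26). For miR-196 the change from the fit, which compares within stage, has the opposite sign to the difference of the means. The miR-17-92 list was placed higher in thoracic ganglia (8 members, 0 passed, 4 adjusted over the list alone, median 0.92, camera adjusted p = 8.49e-05, and adjusted p = 0.0382 with an estimated correlation). Neuronal (median 0.59), signal responsive (0.99) and Dlk1-Dio3 (-0.88) lists were called at adjusted p = 0.000349, 0.000375 and 0.000383, but had adjusted p = 0.204, 0.184 and 0.599 with an estimated correlation. Of the 5 thoracic libraries 3 hold under 1% Dlk1-Dio3 reads, against 5 of the 11 limb-level libraries, and the thoracic E13.5 library among them held 97438 CPM of miR-363 and 135036 of miR-20. Without those libraries 0 miRNAs passed, and the miR-17-92 list had a median of 0.69 (adjusted p = 0.00284, and adjusted p = 0.605 with an estimated correlation). The neuronal, signal responsive and Dlk1-Dio3 lists were then not called (adjusted p = 0.425, 0.409 and 0.279), while the muscle list was placed lower (median -1.20, adjusted p = 0.00788, and adjusted p = 0.605 with an estimated correlation). edgeR called 0 of 245 with 11 at an unadjusted p under 0.05, and DESeq2 called 0. Without the brachial or the thoracic E11.5 library 3 passed (miR-363, miR-20 and miR-92), and without the brachial E12.5 library 2 (miR-363 and miR-19).

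In chicken, axial level gave no call either. miR-196 lay at 1261 ± 1208 CPM in lumbar (n = 4) and 390 ± 284 in brachial libraries (n = 5), a log2 change of 1.69, and at 342 ± 572 in thoracic (n = 3) against 777 ± 894 in limb-level libraries (-2.23). miR-10 lay at 54424 ± 30057 in lumbar, 42889 ± 19478 in brachial and 56495 ± 37318 in thoracic libraries. The miR-17-92 list was placed higher in lumbar than brachial ganglia (6 members, 0 passed, also 0 adjusted over the list alone, median 0.69, camera adjusted p = 0.00818, and adjusted p = 0.714 with an estimated correlation). edgeR called 0 of 88 in both contrasts, with 1 each at an unadjusted p under 0.05, and DESeq2 called 0.

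TrkC is the NT3 receptor of proprioceptive neurons, and its mRNA is not measured in miRNA tables, so the genotype label could not be checked. The barcode partner of the E14.5 mutant library is labelled wild-type lumbar E12.5, and that of the E11.5 mutant library wild-type brachial E13.5. The E14.5 mutant library, labelled brachial, held 12629 CPM (unscaled) of miR-196. The values below speak of the mutant only if the labels hold. No miRNA passed the test between the 2 mutant libraries and wild type, a comparison in which the simulation recovered 0% of 16-fold changes at the observed spread. miR-19 lay at 12441 ± 6780 CPM in mutant (n = 2) and 52898 ± 45226 in E11.5 and E14.5 wild-type libraries (n = 3), a log2 change of -1.75 (SE 0.63), and miR-92 at 7112 ± 5623 and 31733 ± 29687 (-2.28, SE 0.96), both at adjusted p = 0.812. Of the lists, miR-17-92 was placed lower (8 members, 0 passed, also 0 adjusted over the list alone, median -0.69, mean 0.13, camera adjusted p = 0.000238, and adjusted p = 0.0310 with an estimated correlation). Dlk1-Dio3 was placed higher (median 3.17, adjusted p = 0.000235, and adjusted p = 0.570 with an estimated correlation). Signal responsive (-0.95), neuronal (-0.34), Hox (-0.78) and mesenchyme (-0.14) lists were placed lower at adjusted p = 0.000219, 0.00297, 0.0450 and 0.0450, and had adjusted p = 0.133, 0.311, 0.166 and 0.249 with an estimated correlation. edgeR called 0 of 249 with 2 at an unadjusted p under 0.05, and DESeq2 called 0. The wild-type E14.5 library holds 0.00879% Dlk1-Dio3 reads, against 5.59% in the E14.5 and 7.37% in the E11.5 mutant library, and without the E11.5 mutant library 1 miRNA passed, miR-127 (14.96, adjusted p = 0.0330). Without the libraries under 1%, the miR-17-92, Dlk1-Dio3, signal responsive and mesenchyme lists were not called (adjusted p = 0.112, 0.856, 0.856 and 0.856), the neuronal list turned higher (median 1.05, adjusted p = 0.0332) and the Hox list stayed lower (-2.40, adjusted p = 0.0332), both at adjusted p = 0.504 with an estimated correlation.

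Cultured ganglia of E12.5 thoracic level were exposed for 14 h to 10 ng/ml of an agent, with 1 library per agent and 1 shared control. With NT3, a neurotrophin, 2 of 67 miRNAs differed from the control by 4-fold or more, both higher: miR-103/107 by 2.54 on the log2 scale (95% counting interval 2.52 to 2.55) and miR-196 by 2.52. Wnt3a also had 2 of 67, miR-760 at 2.83 (2.32 to 3.41) and miR-196 at 2.36. Wnt5a had 11 of 72, with 10 higher and 1 lower, among them miR-193 at 4.10, the neuronal miR-124 at 2.61 and miR-196 at -2.95. miR-338 was lower than control with all 3 agents (-1.44 with NT3, -1.63 with Wnt5a and -1.53 with Wnt3a). Other named codes were miR-760 (1.80), miR-214 (-1.77) and miR-32 (-1.63) for NT3, miR-29 (2.46) and miR-363 (-1.75) for Wnt5a, and miR-133 (1.93), miR-19 (-1.38) and miR-23 (-1.10) for Wnt3a. For miR-196, agent and partner level differ together, since the barcode partner is labelled thoracic for the control, lumbar for NT3 and Wnt3a, and brachial for Wnt5a. These 3 libraries and the control hold 0.00214% to 0.0111% Dlk1-Dio3 reads.

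The other 5 agents differed from the control in many more codes, and their libraries hold 3.83% to 5.88% Dlk1-Dio3 reads against 0.00332% in the control. An effect of these agents therefore cannot be told apart from the Dlk1-Dio3 division, for the higher codes and for the lower codes given next. Barcode partners of the 5 libraries are mouse-labelled dissected ganglia of E10.5, E11.5 or E12.5, while that of the control is labelled chicken E7. Counts at 4-fold or more were 53 of 86 for Shh (21 higher, 32 lower), 99 of 140 for thyroid hormone 3 (74 and 25), 76 of 114 for the neurotrophin NGF (50 and 26), 88 of 127 for bFGF (62 and 26), and 110 of 151 for PDBU, a phorbol ester that activates protein kinase C (85 and 25). The higher codes include Dlk1-Dio3 codes, 7 for Shh, 24 for thyroid hormone 3, 17 for NGF, 21 for bFGF and 32 for PDBU. The control holds 36 Dlk1-Dio3 reads in all, so a code of this cluster could reach the read limit only through the agent library. miR-127, at 0 reads in the control, was at least 1414-fold higher with Shh, at least 1812-fold with thyroid hormone 3, at least 1418-fold with NGF, at least 1998-fold with bFGF and at least 2315-fold with PDBU. miR-93, at 3 reads in the control, was higher by 12.24 with Shh (11.10 to 14.93), 12.13 with thyroid hormone 3, 12.07 with NGF and 12.10 with PDBU. miR-335 was at least 1471-fold higher with Shh and 1038-fold with NGF, miR-541 at least 633-fold with thyroid hormone 3 and 941-fold with PDBU, and miR-340 and miR-410 at least 813-fold and 778-fold with bFGF.

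Codes lower with these 5 agents were miR-338 (-7.67 with Shh, -7.81 with thyroid hormone 3, -6.92 with NGF, -5.91 with bFGF and -6.96 with PDBU), miR-137 (-5.36) and miR-128 (-5.19) with Shh, miR-363 with NGF (-5.31), bFGF (-7.34) and PDBU (-5.74), and miR-196 with thyroid hormone 3 (-5.37) and bFGF (-6.84). The barcode partners of the thyroid hormone 3 and bFGF libraries are labelled brachial, against thoracic for the control. miR-551 was at least 27.7-fold lower with thyroid hormone 3 and stood at 1 read against 129 with PDBU (-5.97, 95% interval -12.27 to -4.45), and miR-122 at 1 against 203 with NGF (-4.81, -11.12 to -3.31). The neuronal list had medians of -3.03 with Shh, -2.39 with thyroid hormone 3, -2.99 with NGF, -3.30 with bFGF and -2.04 with PDBU (percentiles 8.87, 4.63, 3.23, 1.14 and 5.04 of random lists), against 0.79 with NT3, 0.97 with Wnt5a and 0.52 with Wnt3a (percentiles 96.3, 83.5 and 48.7). For the 5 agents the random lists themselves had medians of -1.69, -1.34, -1.65, -1.22 and -1.24. They were drawn from the eligible codes, some of which reach the read limit only through the agent library. A low percentile was thus partly given in advance and is no test of the list. The eligible members of the signal responsive list with these 5 agents, miR-21, miR-221 and miR-222, had medians from -4.12 with bFGF to -3.23 with PDBU. The activity-linked miR-132 and miR-212 were below the read limit there. With 4 or 5 members eligible, the medians were 0.87 with NT3, 1.15 with Wnt5a and 0.99 with Wnt3a. With the median of the other 7 agents as reference in place of the control, counts were 27 for NT3, 33 for Wnt5a, 30 for Wnt3a, 6 for Shh, 5 for thyroid hormone 3, 4 for NGF, 6 for bFGF and 10 for PDBU, and miR-338 was then higher with NT3 (5.48), Wnt5a (5.28), Wnt3a (5.39) and bFGF (1.01). With total counts alone the counts for NT3 and Wnt5a were 4 and 6.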

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

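All tests of explanations in this part, and the counts over other splits, were chosen only after the results they address had been seen.

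An interaction term in edgeR for a TrkC mutant effect that differs between stages passed for 2 of 249 miRNAs: miR-137 (log2 difference -5.79, SE 1.39, adjusted p = 0.0413) and miR-127 (15.01, SE 3.66, adjusted p = 0.0413). It rests on 1 library each of E11.5 mutant, E14.5 mutant and E14.5 wild type, with their spread taken from other groups. The E14.5 wild-type library, with 0.00879% Dlk1-Dio3 reads, held 0 reads of miR-127 and 43096.5 CPM of miR-137. Without it the interaction cannot be computed, so a difference in the mutant effect is not established. The chicken-labelled libraries, where no such signal belongs, held 142 reads of Dlk1-Dio3 miRNAs, of which miR-377 gave 122.

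The share of the mammal-only Dlk1-Dio3 cluster lay at or under 0.0259% in 12 mouse-labelled libraries and at or above 3.83% in 15. Lower depth is argued against, since the highest upper 95% Wilson limit among the 12 is 0.0329%, and developmental stage is argued against for E12.5 to E14.5, where all 3 labelled stages have libraries on both sides of 1%, among wild-type dissected libraries only at E13.5 (those under 1% at E12.5 are cultured, and the one above at E14.5 is the mutant). For E18.5 and P16, stage cannot be told apart from the exchange described next, because their 6 libraries, at 0.00733% or less, all lie on one side and in 1 pool. A candidate explanation for the division is that the names of the 2 sequencing pools were exchanged: 19 barcodes occur in both pools, and 26 of the 26 mouse-labelled libraries with a barcode partner lie on the side that the partner's species label gives (chance of this division 1.04e-07). The exchange would put chicken RNA behind the 12 mouse-labelled libraries and mouse RNA behind the chicken-labelled ones, which the 22 reads of the bird miRNA miR-2954 in the latter do not settle, and it was not tested against records of the sequencing.

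The order of miR-196 by axial level gave a separate look at the same explanation. Under the labels the more caudal library held more miR-196 in 71 of 143 pairs (49.7%), and with the level of the barcode partner in 140 of 143 (97.9%, one-sided permutation p = 1e-05, the smallest that 100000 permutations give). Counting error is argued against, since the 95% intervals overlapped in only 16.7% of the 72 misordered pairs. These values are consistent with exchanged pool names as a hypothesis, found and tested on the same data. A difference between stages cannot give the spread of miR-196 among the 9 cultured libraries of 1 labelled stage and level (16.3 to 12838 CPM), where an effect of the agents stays open, and among the dissected stages a difference in its axial pattern was not tested.

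Counts were compared with other splits of the same libraries. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. E13.5 against E12.5 gave 2 miRNAs, 2 of the 10 splits gave as many, and the highest other split gave 46 (brachial E13.5 with brachial and thoracic E12.5). E18.5 against E13.5 gave 152, 1 of 10 as many, and the highest other 106 (thoracic E18.5 with brachial and lumbar E13.5, which sets the thoracic E13.5 library against the other E13.5 libraries). Chicken E7 against E6 gave 1, 2 of 10 as many, and the highest other 35 (brachial E7 with thoracic and lumbar E6). Splits that call many more than the labelled groups, 46 and 35, point to a structure of the samples other than stage. Where the labelled groups gave 0, every split gives at least as many by construction, and the counts say nothing about chance. These are P16 against E18.5 (10 of 10 splits, highest other 0), chicken E6 against E5 (10 of 10, highest other 1) and each of the 4 axial contrasts (100 of 100 splits, highest other 1). No split of 3 against 3 follows the pools.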

How the results depend on the processing

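Sequencing pool as a term, omission of the mouse-labelled libraries under 1% Dlk1-Dio3 reads, and library omissions for detection counts were chosen after the data were seen. Of the values for named miRNAs under alternatives, 515 kept direction and side of the threshold (or moved less than their spread), 65 kept direction but missed the threshold, 76 moved and 10 reversed. Of the values for whole comparisons, 197 stayed within 1.5 times or their spread, 54 moved and 4 reversed. The cause was not tested except where fewer libraries or another reference are the setting itself.

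RLE factors and total counts each left 0 calls for mouse E13.5 against E12.5, no axial term left 1, and omission of the libraries under 1% gave 1. Pool as a term, which rests on the lumbar E13.5 library, gave 4, the same codes as without that library. The omission of the libraries under 1% gave 5 for mouse lumbar against brachial. DESeq2 called 6 for chicken E6 against E5, 5 for E7 against E6 and 2 for E9 against E7. No axial term gave 5 for chicken E7 against E6, and omission of the library with conflicting labels 0. For mouse thoracic against limb levels, no count filter gave 1 and omission of the library with conflicting labels 3. RLE factors moved the median log2 change of all miRNAs by -0.12 (E12.5 against E11.5), -0.15 (E13.5), -0.29 (E18.5), -0.17 (P16) and -0.25 (mouse lumbar against brachial). Total counts moved it by -0.26 (E13.5), -0.37 (E18.5), -0.15 (chicken E7), -0.22 (mouse thoracic), -0.11 (chicken thoracic) and 0.42 (TrkC).

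With each library left out in turn, calls ranged from 1 to 4 for mouse E13.5 against E12.5, 67 to 202 for E18.5 against E13.5, 0 to 12 for chicken E6 against E5, 0 to 36 for E7 against E6, 0 to 3 for mouse thoracic against limb levels, and 0 to 1 for the TrkC mutant. Where an omission leaves a group with 1 library, that library is assumed to vary like the other groups.

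With an estimated correlation, the number of lists past the threshold was 1 for mouse E13.5, thoracic against limb levels, and the TrkC mutant, and 0 for mouse E18.5, P16 and lumbar against brachial and for chicken E6, E7, E9 and lumbar against brachial. At the preset correlation but without the mouse-labelled libraries under 1% Dlk1-Dio3 reads, the number was 2 for mouse E13.5, 1 for lumbar against brachial, 2 for thoracic against limb levels and 2 for the TrkC mutant.

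With the median of the other 7 agents as reference, 4-fold counts were 27 for NT3, 33 for Wnt5a, 30 for Wnt3a, 6 for Shh, 5 for thyroid hormone 3, 4 for NGF, 6 for bFGF and 10 for PDBU. Reversed log2 ratios were miR-760 (-0.89) and miR-338 (5.48) for NT3, miR-29 (-0.63), miR-363 (3.55) and miR-338 (5.28) for Wnt5a, miR-338 (5.39), miR-19 (0.42) and miR-23 (0.24) for Wnt3a, miR-127 (-0.00176) for Shh and miR-338 (1.01) for bFGF. Total counts gave 4 for NT3 and 6 for Wnt5a. A prior count of 5 kept each 4-fold count within 1.5 times and moved 14 named ratios, all over libraries with 0 or 1 read, for example miR-127 with PDBU from 12.76 to 10.44.

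Detection differences reversed at a limit of 3 reads for P16 against E18.5 (-0.333) and chicken E6 against E5 (1.67). The P16 difference was 0 without thinning. Chicken E6 against E5 ranged from -1.33 to 1 with libraries left out, reversing without the thoracic E6 (1) and the lumbar E5 library (0.667). E18.5 against E13.5 cannot be computed without libraries under 1%.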

Other observations

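The levels in this part were chosen for description after their values were seen, and let-7 passed the edgeR test in none of the 12 comparisons. let-7, the developmental timing family, lay in chicken-labelled ganglia at 183270 CPM in the E4 library, 272353 ± 48727 at E5, 333884 ± 50715 at E6, 223438 ± 88144 at E7 (SD, n = 3 each) and 149354 ± 18503 at E9 (n = 2). In mouse-labelled ganglia it lay at 95914 CPM in the E10.5 library, 54135 ± 33017 at E13.5, 77342 in the E14.5 wild-type library, 85774.5 ± 16153 at E18.5 and 107333 ± 26919 at P16 (n = 3 where SD is given). E4, E10.5 and E14.5 have 1 library each. The wild-type E14.5, the E18.5 and P16 libraries and the thoracic E13.5 library lie under 1% Dlk1-Dio3 reads, and the E10.5 and other E13.5 libraries above. The mouse-labelled series thus crosses that division and cannot be read as a course over stages alone. Nor can the chicken-labelled series, where stage and the labelled stage of the barcode partner differ together. The partner is labelled E13.5 for the E4 library, and E14.5, E18.5 or P16 for the E5 and E6 libraries. At E7 the brachial library, with a partner labelled P16, held the highest value, 325199 CPM, against a lowest of 170901. Partners of the other E7 and both E9 libraries are cultured E12.5 ganglia.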
